A study of Homo sapiens with 40 samples.

How the data were processed

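The series holds 40 samples of A549 cells, of which the 8 polyA RNA-seq libraries were used and the 32 ChIP-seq and input samples were not analysed here. Per the labels, cells were kept in charcoal-stripped serum before treatment, and RNA was taken after 24 hours in ethanol or 100 nM dexamethasone. The labels name the groups by hairpin, and the arm written with the prefix K was read as the KDM1A hairpin from the title and the sample characteristics. The count of KDM1A itself was lower in that arm.

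The authors deposited estimated counts per gene, made with Salmon per the labels, as the mean and the SD of the 2 libraries of each group, without scaling for library size. Every mean was a multiple of 0.5, and mean and SD together gave a pair of whole counts for every gene and group with an SD taken with n - 1, so the pairs were recovered without their order. The authors deposited log2 fold changes with standard errors and adjusted p-values, which are DESeq2 output per the labels, for 3 comparisons: dexamethasone in scramble cells, dexamethasone in KDM1A shRNA cells, and the KDM1A hairpin in ethanol. The direction of each was checked by regression on the log2 group means. Adjusted p-values of exactly 1, held by 27.1%, 34.9% and 31% of genes in the order above, were taken as genes that had not been tested, which left 16924, 15124 and 16022 tested genes. The deposited transcription start sites carry no stated numbering base, and no genome build is given for the RNA-seq samples in the sources used here, so only chromosomes are printed. Versions of Salmon and DESeq2 and the strand of counting are not given in the sources used here.

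For these 3 comparisons the authors' deposited fold changes and adjusted p-values were used, and an adjusted p under 0.05 counted as a change. The KDM1A hairpin in dexamethasone and the interaction were not among them and were tested with limma 3.58.1 in R 4.3.3, as a moderated test on log2 of the TMM-scaled count plus 1, over the 16263 genes with a mean over the 4 groups of at least 10. Scaling factors were taken from the group means, so in every limma and edgeR fit both libraries of a group were divided by the same factor. A depth difference between the libraries of a group was not removed and stayed in the spread. The tests of genes and of gene lists were 2-sided and their p-values were adjusted by Benjamini-Hochberg, while the permutation test of neighbouring genes was 1-sided and not adjusted. Tables and bootstrap intervals were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Log2 fold changes are given with the standard error (SE) of their fit. Bootstrap intervals resampled genes, and bounds with a shared error added 2 standard errors as if all genes of a list had the same error. Where a group held 1 to 3 counts, the ratio of scaled counts is given with a 95% exact counting interval, which covers counting error only. Over genes with a mean of at least 10000, the spread within groups left after the median depth difference of the pair was at least 7.56 to 15.1 times the counting variance. These are lower bounds, since the smaller residual of both orders of a pair was taken.

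The tests, the 24 gene lists and most alternatives were chosen before the data were examined. The lists covered glucocorticoid-induced, inflammatory, ion transport, metallothionein, clock, interferon, cell cycle, epithelial, mesenchymal, alveolar, KDM1A complex, histone methylation, receptor cofactor, p53 target, unfolded protein and amino acid stress, sterol, hypoxia, NRF2, TGF-beta and neuronal genes, markers of fibroblasts, leukocytes and endothelium, and mitochondrially encoded mRNAs. Lists with at least 5 tested genes were tested with limma's cameraPR at a preset correlation of 0.01, adjusted over 112 pairs of list and comparison, of which 41 passed. An estimated correlation was not possible because the identity of the replicates was unknown, so 0.05 was run beside it, as were a rank-based version and one over genes with a mean of at least 100. Named genes were KDM1A, NR3C1, the 6 highest and 6 lowest log2 fold changes of each main comparison among genes with a symbol, an adjusted p under 0.05 and a mean of at least 100, and up to 3 called members with the largest absolute change from each list with a called test or at least 3 called members. For the interaction the rule took up to 5 genes in each direction. The text describes part of the genes that the rule named.

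Alternatives were an adjusted p of 0.01, a minimum absolute log2 fold change of 1, a mean of at least 100, no filter, limma for the deposited comparisons, a pseudocount of 10, a mean-variance trend and median-of-ratios scaling. Added after the data were seen were edgeR 4.0.16 on the recovered pairs, a Wald test with the fold changes and standard errors that the deposited comparisons imply, a slope corrected for error, a slope without cell cycle genes, and list tests on the statistics of the other fit. The plan had named edgeR for counts per library and limma for group means and SDs alone. The deposit held the latter, and limma stayed the main test although whole counts could be recovered. The fits were tested on simulated data with 200 changed genes among 16300, with DESeq2 1.42.0 standing in for the authors' fit. Genes were drawn independently at the dispersion trend, without scatter of single genes around it, which can favour the fits that use a trend. Depth differences within groups entered both the dispersion and the simulated means. Changed genes had a mean of at least 100 and no other response to dexamethasone. For the hairpin in dexamethasone limma recovered 40 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2, and 8.55% of its calls were not changed. For the interaction limma recovered 0 of 100 and 89 of 100, edgeR 79 and 99, the trend 76 and 100, and the implied Wald test 84 and 99. The list test called the planted list and 0 of 40 random lists. Since the simulated genes were independent, this does not test lists whose genes share an error.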

Results

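A549 cells, an established human lung adenocarcinoma line, were profiled in 40 samples, of which 8 were polyA RNA-seq libraries and 32 were ChIP-seq or input samples. The ChIP-seq samples were not analysed here. The RNA-seq libraries fell into 4 groups of 2. Cells carried a scramble short hairpin RNA (shRNA) or one that the labels tie to KDM1A, and each arm was given ethanol or 100 nM dexamethasone, a synthetic glucocorticoid, for 24 hours. The series title names the glucocorticoid receptor and KDM1A in gene activation at enhancers, and the 4 groups compare expression and its response to dexamethasone between the hairpins. The tables covered 23231 genes, of which 21153 carried a symbol. The mean total estimated count per library was 18722100 in scramble cells in dexamethasone, 20807800 in scramble cells in ethanol, 18554700 in KDM1A shRNA cells in dexamethasone and 17364700 in KDM1A shRNA cells in ethanol. The 2 libraries of a group differed by a median fold of 1.04 to 1.13 per gene. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values of single genes measure a spread between libraries that may be technical. The camera p-values compare the genes of a list with all other genes at a preset correlation and do not measure a spread between libraries or cultures. Every comparison below rests on 2 libraries per group, and comparisons that share a group are not independent of each other.

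KDM1A (ENSG00000004487, chromosome 1), the histone demethylase that the hairpin targets, had an authors' mean count of 1414.5 (SD 118.1, n = 2) in scramble cells in ethanol and 1458.5 (SD 183.1, n = 2) in dexamethasone. In KDM1A shRNA cells its authors' mean count was 659.5 (SD 28.99, n = 2) in ethanol and 637 (SD 28.28, n = 2) in dexamethasone. In the authors' deposited table KDM1A fell by 0.81 on the log2 scale (SE 0.12, adjusted p = 3.13e-10) with the hairpin in ethanol. In dexamethasone limma gave a log2 fold change of -1.25 (SE 0.13, adjusted p = 0.00386). The values in ethanol and dexamethasone come from different fits, so they do not compare the depth of the knockdown between the media. Dexamethasone itself gave KDM1A log2 fold changes of 0.24 in scramble cells (adjusted p = 0.112) and -0.04 in KDM1A shRNA cells (adjusted p = 0.914) in the authors' deposited table. NR3C1 (ENSG00000113580, chromosome 5), which encodes the glucocorticoid receptor, had authors' mean counts between 2991 and 3894.5 in the 4 groups. In the authors' deposited table its adjusted p was 0.062 for dexamethasone in scramble cells, 0.709 in KDM1A shRNA cells and 0.059 for the hairpin in ethanol. For the hairpin in dexamethasone NR3C1 had a limma log2 fold change of -0.25 (adjusted p = 0.269), while a Wald test with the standard errors that the authors' deposited table implies gave -0.27 (adjusted p = 0.000292).

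The response to dexamethasone in scramble cells was measured first, where KDM1A was not targeted. Among genes with a mean count of at least 100, the highest log2 fold changes in the authors' deposited table were those of CDH16, a cadherin of kidney epithelium, at 7.18 (SE 0.32), SFTPD, the alveolar surfactant protein D, at 6.40 (SE 0.42), STAC2 at 6.10 (SE 0.45), the adhesion molecule SDK2 at 5.80 (SE 0.18) and the kinin precursor KNG1 at 5.58 (SE 0.51). EDN3, which encodes endothelin 3, also rose, from 3 counts over both ethanol libraries to 567 in dexamethasone, a scaled ratio of 210 (95% exact counting interval 71.6 to 1020). The lowest log2 fold changes in the authors' deposited table were those of the cadherin CDH6 at -4.38 (SE 0.40), the cytokine TNFSF15 at -4.10 (SE 0.22), the replication factor MCM10 at -3.90 (SE 0.39), FER1L6 at -3.85 (SE 0.38), the cytokine IL11 at -3.80 (SE 0.42) and PTHLH, which encodes parathyroid hormone-related protein, at -3.69 (SE 0.30). In all, 4313 of 16924 tested genes changed in the authors' deposited table, with 1943 higher and 2370 lower.

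Of 34 tested genes known to be induced by glucocorticoids, 28 rose in scramble cells, or 29 adjusted over the list alone, and the list's median log2 fold change was 2.05 (camera adjusted p = 5.97e-131). They included the lipid droplet protein gene CIDEC at 5.37 (SE 0.16) and the transcription factor TFCP2L1 at 4.81 (SE 0.15) in the authors' deposited table. Of 12 tested airway ion and fluid transport genes, 7 rose and 2 fell, as many as adjusted over the list alone (median 0.61, camera adjusted p = 4.39e-06). All subunits of the epithelial sodium channel on that list rose in the authors' deposited table, SCNN1B by 3.77 (SE 0.15), SCNN1G by 3.71 (SE 0.53) and SCNN1A by 3.38 (SE 0.12) on the log2 scale. The metallothioneins MT1X, MT2A and MT1F, which bind metal ions, rose by 4.56 (SE 0.13), 2.89 (SE 0.06) and 2.44 (SE 0.31) in the authors' deposited table, in all 3 tested members and as many adjusted over the list alone. These paralogs are nearly identical and share reads, so the values of single members are uncertain. Of 20 tested epithelial genes, 10 rose and 3 fell, as many as adjusted over the list alone (median 0.42, camera adjusted p = 4.16e-06). Among them were the keratin KRT7 at 1.64 (SE 0.04) and E-cadherin, CDH1, at 1.03 (SE 0.08) in the authors' deposited table. A rank-based test did not call the ion transport list (adjusted p = 0.145) or the epithelial list (adjusted p = 0.122).

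All 33 S phase and mitotic genes fell in scramble cells, and all 33 adjusted over the list alone, with a median of -1.76 (camera adjusted p = 2.56e-34). The replication licensing factor CDC6 was at -3.67 (SE 0.26), the ribonucleotide reductase subunit RRM2 was at -3.05 (SE 0.17) and the transcription factor E2F1 at -2.90 (SE 0.23) in the authors' deposited table. Of 17 tested inflammatory genes 10 fell, with 12 lower and 1 higher adjusted over the list alone (median -1.11, camera adjusted p = 2.12e-29). IL11, the prostaglandin synthase PTGS2 at -3.08 (SE 0.07) and the adhesion molecule VCAM1 at -3.03 (SE 0.51) had the lowest values of that list in the authors' deposited table. Of 23 oxidative stress and xenobiotic (NRF2) genes 15 fell and 5 rose, or 15 and 6 adjusted over the list alone (median -0.34, camera adjusted p = 1.12e-16). Among them were the aldehyde dehydrogenase ALDH3A1 at -2.14 (SE 0.05) and the cystine transporter SLC7A11 at -1.86 (SE 0.06) in the authors' deposited table. Of 22 unfolded protein response and amino acid stress genes 14 fell and 4 rose, or 15 and 5 adjusted over the list alone (median -0.62, camera adjusted p = 3.4e-07). CHAC1, a glutathione-degrading enzyme, was at -2.12 (SE 0.42) in the authors' deposited table. Of 20 sterol metabolism genes 14 fell and 1 rose, by all genes and adjusted over the list alone (median -0.57, camera adjusted p = 0.000436). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, was at -1.62 (SE 0.16) in the authors' deposited table. Of 35 tested interferon-stimulated genes 16 fell and 1 rose, or 18 and 2 adjusted over the list alone (median -0.65, camera adjusted p = 0.00539). This call was lost with a preset correlation of 0.05 (adjusted p = 0.0835).

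The other lists were not called for dexamethasone in scramble cells by the camera test. Of 22 p53 targets 9 rose and 3 fell in the authors' deposited table (camera adjusted p = 0.272), 7 mesenchymal genes rose and 7 fell of 24 (0.721), and 4 clock genes rose and 3 fell of 19 (0.806), as many as adjusted over the list alone. Of 21 TGF-beta response genes 7 rose and 7 fell, or 7 and 9 adjusted over the list alone (0.857). SNAI2, a transcription factor of epithelial-mesenchymal transition, rose by 3.67 (SE 0.44) and the clock gene PER1 by 3.19 (SE 0.15) in the authors' deposited table. Of 20 members of KDM1A co-repressor complexes 4 rose and 4 fell (camera adjusted p = 0.743), and of 29 histone methylation enzymes 5 rose and 3 fell (0.709), by both adjustments in each list, the second adjusted over the list alone. Of the complex members limma called 1 higher and no other, and edgeR 5 higher and 2 lower. Of the methylation enzymes limma called 1 higher and 2 lower, and edgeR 2 and 3. Of 21 receptor cofactors and steroid enzymes 5 rose and 4 fell, or 6 and 5 adjusted over the list alone (0.486), while limma called 2 and 2 and edgeR 4 and 2. The cortisol-inactivating enzyme HSD11B2 was at 3.88 (SE 0.26) in the authors' deposited table. Of 20 hypoxia genes 3 rose and 6 fell, or 4 and 8 adjusted over the list alone (0.932), and of 20 tested neuronal genes 1 rose and 7 fell, also adjusted over the list alone (0.0786). Of 12 tested alveolar and secretory genes 4 rose and 3 fell, or 4 and 4 adjusted over the list alone (0.552, upward), with a median of -0.09 against a mean of 0.33. Markers of fibroblasts fell in 2 of 6 tested members (0.737), of leukocytes in 3 of 5 (0.24) and of endothelium in 3 of 8 (0.56), as many as adjusted over the list alone. The leukocyte marker LYZ had authors' mean counts of 113.5 in ethanol and 25 in dexamethasone, and CD68 had 2925 and 1789.5 and was at -0.55 (SE 0.09) in the authors' deposited table. The leukocyte list was called downward by rank (adjusted p = 0.0426) and with limma statistics (adjusted p = 0.00457), and the neuronal list with a mean count of at least 100 (adjusted p = 0.00854) and with limma statistics (adjusted p = 0.00587). Of 9 mitochondrially encoded mRNAs, a list chosen as a rough check of RNA quality, 1 rose, also adjusted over the list alone (0.552). Whether the list tracks RNA quality here was not tested. A minimum absolute log2 fold change of 1 left 1354 genes. The replicate order needed to estimate a correlation between the genes of a list was not given in the sources used here.

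In KDM1A shRNA cells dexamethasone gave a fold change of the same sign in 95.6% of the genes called in scramble cells. EDN3 at 5.59 (SE 0.57), CDH16 at 5.28 (SE 0.29), KNG1 at 4.69 (SE 0.56), SFTPD at 4.60 (SE 0.44) and STAC2 at 4.43 (SE 0.42) had the highest log2 fold changes in the authors' deposited table, with ALPP, a placental alkaline phosphatase that shares sequence with its paralogs, at 4.41 (SE 1.10). The lowest were IL11 at -3.22 (SE 0.37), TNFSF15 at -3.01 (SE 0.20), STC1, which encodes stanniocalcin, at -2.96 (SE 0.28), and CXCL5, a neutrophil chemokine, at -2.80 (SE 0.04) in the authors' deposited table. In all, 3021 of 15124 tested genes changed in the authors' deposited table, with 1398 higher and 1623 lower. Over the 15124 genes tested in both arms, 1138 genes rose in both, of 1921 in scramble and 1398 in KDM1A shRNA cells, where 177.6 would be shared if the calls were independent. The corresponding count of genes that fell in both was 1322, of 2341 and 1623, against 251.2 if independent.

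Of 33 tested glucocorticoid-induced genes 29 rose and 2 fell in KDM1A shRNA cells, as many as adjusted over the list alone (median 2.00, camera adjusted p = 4.42e-129). The receptor cochaperone FKBP5 was at 4.13 (SE 0.08) and CIDEC at 4.26 (SE 0.14) in the authors' deposited table. Of 15 tested inflammatory genes 14 fell, and 14 adjusted over the list alone (median -1.42, camera adjusted p = 2.1e-51). VCAM1 was at -2.91 (SE 0.47) in the authors' deposited table. Of 33 cell cycle genes 30 fell, or 31 adjusted over the list alone (median -0.75, camera adjusted p = 1.87e-11). CDC6 was at -2.15 (SE 0.22) and E2F1 at -1.49 (SE 0.20) in the authors' deposited table. Of 16 tested epithelial genes 8 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 9.92e-08). KRT7 was at 1.08 (SE 0.04) in the authors' deposited table. Of 12 tested ion transport genes 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000185, upward), with a median of -0.001 and a mean of 0.68. A rank-based test did not call this list (adjusted p = 0.599) or the epithelial list (adjusted p = 0.122). The sodium channel subunit SCNN1G was at 4.03 (SE 0.51) in the authors' deposited table. NRF2 genes fell in 16 of 23 members and rose in 2, also adjusted over the list alone (median -0.51, camera adjusted p = 3.64e-32). Stress genes fell in 9 of 22 and rose in 3, also adjusted over the list alone (median -0.27, camera adjusted p = 0.0011). Interferon genes fell in 12 of 33 tested members and rose in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00526, and adjusted p = 0.0782 with a correlation of 0.05). Sterol genes fell in 8 of 20 and rose in 1, also adjusted over the list alone, without a call of the list (camera adjusted p = 0.338). By limma 7 interferon, 5 sterol and 11 NRF2 genes fell and by edgeR 15, 9 and 14. Of 9 mitochondrially encoded mRNAs 7 rose in the authors' deposited table, or 8 adjusted over the list alone (median 0.17, camera adjusted p = 0.00181). MT-CO1 was at 0.29 (SE 0.03) in the authors' deposited table. By edgeR 3 of these 9 rose, and limma called no member, giving MT-CO1 0.29 (adjusted p = 0.148), against 8 at an unadjusted p under 0.05 in the authors' deposited table. With limma statistics the list was not called (adjusted p = 0.239). PPARGC1A, at 2.94 (SE 0.91) in the authors' deposited table, had authors' mean counts of 10.5 in ethanol and 7.5 in dexamethasone, and the limma value was -0.69, so its direction is not settled. Leukocyte markers fell in 3 of 5 tested members, also adjusted over the list alone (camera adjusted p = 0.184, adjusted p = 0.0426 by rank and 0.00116 with limma statistics). Neuronal genes fell in 6 of 16 tested members and rose in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0813, adjusted p = 0.0153 with a mean count of at least 100 and 0.00257 with limma statistics). The mesenchymal list had a median of -0.23, a mean of 0.14 and a downward test (camera adjusted p = 0.629). A minimum absolute log2 fold change of 1 left 714 genes.

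The size of the response was compared between the arms over the 4313 genes called in scramble cells. The slope of the KDM1A shRNA fold changes on the scramble ones, through the origin, was 0.572 in the authors' deposited table, the median ratio was 0.654, and 84.9% of these genes had a smaller fold change in KDM1A shRNA cells, against 60.5% of the genes called in KDM1A shRNA cells. Genes chosen for a change in scramble cells regress toward 0 in any second measurement, and over the 3021 genes called in KDM1A shRNA cells the slope was 0.767. Over the fixed list of glucocorticoid-induced genes, with 33 members tested in both arms, it was 0.822. The cell cycle list had a slope of 0.45 and the inflammatory list, with 15 members, a slope of 0.942. The inflammatory list had a median ratio of 1.13, and 33.3% of its members had a smaller fold change in KDM1A shRNA cells. Genes are not independent replicates, so no p-value was taken across them.

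**Figure D1:**
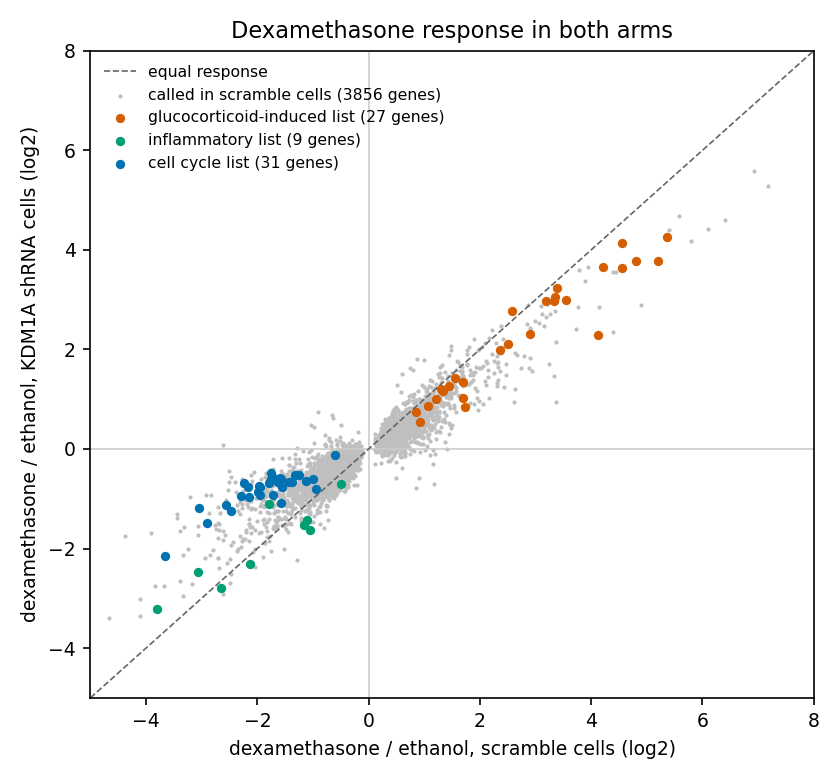
Each point is a gene with a mean count of at least 100 called for dexamethasone in scramble cells (3856 genes), with its log2 fold change in the authors' deposited table in scramble cells on the horizontal axis and in KDM1A shRNA cells on the vertical axis, both unitless log2 ratios. The dashed line marks equal responses, and colours mark 27 glucocorticoid-induced, 9 inflammatory and 31 cell cycle genes, the last lying closer to 0 on the vertical axis than on the horizontal one.

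The hairpin against KDM1A was compared with the scramble one in ethanol, which measures the difference between the hairpins without hormone. The stress regulator NUPR1 at 3.22 (SE 0.34), the semaphorin SEMA6B at 2.61 (SE 0.20), the tight junction protein CGN at 2.27 (SE 0.28), PIK3AP1 at 2.26 (SE 0.34), the stress cytokine GDF15 at 2.13 (SE 0.10) and the lipid transporter ABCA12 at 2.01 (SE 0.26) had the highest log2 fold changes in the authors' deposited table. The lowest in the authors' deposited table were the cystatin CST1 at -2.83 (SE 0.20), IGFBP5, which binds insulin-like growth factors, at -2.70 (SE 0.24), TM4SF4 at -2.60 (SE 0.20), the adhesion receptor ADGRL2 at -2.50 (SE 0.36), SSTR5-AS1 at -2.10 (SE 0.25) and the airway secretory protein BPIFB1 at -2.01 (SE 0.16). CST1 has close paralogs and SSTR5-AS1 is an antisense gene, so both values are uncertain where the strand of counting is not given in the sources used here. In all, 1873 of 16022 tested genes changed in the authors' deposited table, with 661 higher and 1212 lower. The balance turned among the 301 genes with an absolute log2 fold change of at least 1, of which 184 were higher and 117 lower in the authors' deposited table.

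Of 22 p53 target genes 20 were higher in KDM1A shRNA cells in ethanol, as many as adjusted over the list alone (median 0.95, camera adjusted p = 3.61e-59). Beside GDF15 they included the antiproliferative gene BTG2 at 1.51 (SE 0.15) in the authors' deposited table. Of 12 tested alveolar and secretory genes 5 were lower, also adjusted over the list alone (median -0.13, camera adjusted p = 2.57e-06). The gel-forming mucins MUC5AC at -1.61 (SE 0.12) and MUC5B at -1.48 (SE 0.10) were the lowest of them in the authors' deposited table, and as neighbouring paralogs listed at the same start site their reads may not be fully separated. Of 16 tested inflammatory genes 6 were lower and 1 higher, also adjusted over the list alone (median -0.27, camera adjusted p = 2.75e-06). The monocyte chemokine CCL2 was at -0.99 (SE 0.11) in the authors' deposited table. NRF2 genes were lower in 14 of 23 members and higher in 6, or 14 and 7 adjusted over the list alone (median -0.18, camera adjusted p = 2.46e-05). By limma 2 were lower and 2 higher and by edgeR 9 and 3, and the NRF2 list was not called with limma statistics (adjusted p = 0.274) or by rank (adjusted p = 0.145). The haem oxygenase HMOX1 was among the higher ones at 1.28 (SE 0.14) in the authors' deposited table. Of 12 tested ion transport genes 4 were lower and 1 higher, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00308). The cotransporter SLC12A2 was at -0.71 (SE 0.04) in the authors' deposited table. Sterol genes were lower in 5 of 20 members, or in 8 with 1 higher adjusted over the list alone (camera adjusted p = 0.00235). INSIG1 was at -0.78 (SE 0.15) in the authors' deposited table. Epithelial genes were higher in 5 of 18 tested members and lower in 2, also adjusted over the list alone (median 0.27, camera adjusted p = 0.00364). The adhesion molecule EPCAM was at 1.48 (SE 0.28) in the authors' deposited table. Hypoxia genes were lower in 6 of 20 members and higher in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.129 with a correlation of 0.05, and adjusted p = 0.0728 with a mean count of at least 100). By limma 1 hypoxia gene was lower and by edgeR 6 were lower and 1 higher, and 3 epithelial genes were higher by limma and 6 by edgeR, with the lower calls lost in both. Limma called 3 inflammatory, 2 ion transport, 2 sterol and 3 alveolar genes lower and edgeR 6, 4, 5 and 4. A rank-based test did not call the alveolar (adjusted p = 0.238), inflammatory (0.0522), ion transport (0.139) or epithelial (0.169) lists.

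Among lists without a call in ethanol, 2 of 33 cell cycle genes were higher, also adjusted over the list alone (median 0.02, camera adjusted p = 0.348), with 1 higher by edgeR and no limma call beside 4 higher and 1 lower at an unadjusted p under 0.05 in the authors' deposited table. Of the 33 tested glucocorticoid-induced genes 7 were higher and 9 lower, or 7 and 10 adjusted over the list alone (0.552), while limma called 3 higher and 2 lower and edgeR 5 and 8. The glucocorticoid-induced transcription factor KLF9 was at 1.81 (SE 0.47) and IGFBP1, which binds insulin-like growth factors, at -1.44 (SE 0.11) in the authors' deposited table. The smooth muscle actin gene ACTA2 was at 1.77 (SE 0.17) in the authors' deposited table, and since it lies at the same locus as the p53 target FAS on the other strand its value is uncertain. The neuronal sodium channel genes SCN2A and SCN3A rose from very low counts. SCN2A had 86 counts over both KDM1A shRNA libraries and 2 over both scramble libraries, a scaled ratio of 47.7 (95% exact counting interval 12.8 to 401), and SCN3A had 101 and 3, a ratio of 37.4 (12.4 to 184). The stress list had a median of -0.08, a mean of 0.02 and a downward test (camera adjusted p = 0.552). With limma from group means and SDs 706 genes changed, of which 51% were higher, against 35.3% in the authors' deposited table. Among named genes, the calls of CXCL3, MUC1, CLDN3 and ZMYM3 in the authors' deposited table were among those not made by that limma fit.

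The same contrast in dexamethasone was tested with limma on log2 counts. SEMA6B rose by 4.22 (SE 0.13), the thyroid hormone deiodinase DIO2 by 3.00 (SE 0.23), the vesicle trafficking GTPase RAB3B by 2.90 (SE 0.18), the planar polarity gene VANGL2 by 2.72 (SE 0.13), RBPMS2 by 2.66 (SE 0.30) and ANKRD29 by 2.49 (SE 0.23) on the log2 scale in KDM1A shRNA cells. The lowest values were those of CST1 at -2.67 (SE 0.16), IGFBP5 at -2.60 (SE 0.21), CST2 at -2.50 (SE 0.17), the secretory protein gene PIP at -2.32 (SE 0.29), TM4SF4 at -1.96 (SE 0.23) and BPIFB1 at -1.94 (SE 0.10). CST1 and CST2 are close paralogs that share reads. In all, 1390 of 16263 tested genes changed by limma, with 792 higher and 598 lower. Over 15990 genes tested in both media, 248 were higher with the hairpin in both ethanol (657) and dexamethasone (776), where 31.9 would be shared if independent, and 291 were lower in both (1212 and 592), against 44.9.

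In dexamethasone 27 of 33 cell cycle genes were higher in KDM1A shRNA cells, or 32 adjusted over the list alone (median 1.14, camera adjusted p = 2e-46). The mitotic kinase gene CDK1 was higher by 1.66 (SE 0.11), CDC6 by 1.62 (SE 0.30) and the mitotic ubiquitin-conjugating enzyme UBE2C by 1.56 (SE 0.12). Of 22 p53 targets 16 were higher, or 18 adjusted over the list alone (median 0.97, camera adjusted p = 8.43e-34). Among them were GDF15 at 2.40 (SE 0.12), the mitochondrial reductase FDXR at 1.56 (SE 0.11) and the stress gene SESN2 at 1.47 (SE 0.13). Of 33 tested glucocorticoid-induced genes 12 were lower and 2 higher, or 16 and 2 adjusted over the list alone (median -0.42, camera adjusted p = 7.32e-07). Among them were IGFBP1 at -1.91 (SE 0.16) and the protease inhibitor SERPINA3 at -1.56 (SE 0.19). The metallothioneins were lower in all 3 tested members, also adjusted over the list alone, with MT2A at -1.03 (SE 0.13). Inflammatory genes were lower in 7 of 17 tested members and higher in 2, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.00181). CCL2 was at -1.57 (SE 0.14). Alveolar and secretory genes were lower in 4 of 12 tested members, or 5 adjusted over the list alone (camera adjusted p = 0.00159). MUC5AC was at -1.90 (SE 0.18). Ion transport genes were lower in 3 of 12, or 5 adjusted over the list alone (camera adjusted p = 0.00226), with the aquaporin AQP3 at -1.46 (SE 0.14). Stress genes were higher in 5 of 22, or 5 with 1 lower adjusted over the list alone (camera adjusted p = 0.00981, and adjusted p = 0.0767 with a correlation of 0.05), with the serine synthesis enzyme PHGDH at 2.14 (SE 0.13). Neuronal genes were higher in 4 of 19 tested members and lower in 1, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.099 with a correlation of 0.05). SCN2A had 116 counts over both KDM1A shRNA libraries against 1 over both scramble libraries, a scaled ratio of 111 (95% exact counting interval 19.5 to 4420). SCN3A had 50 against 5, a ratio of 9.56 (3.83 to 30.7), and the Wald test did not call it. Receptor cofactors were lower in 3 of 21, or 4 adjusted over the list alone (camera adjusted p = 0.0183, and adjusted p = 0.1 with a correlation of 0.05). NRF2 genes were lower in 5 of 23 with 2 higher, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.159 with a correlation of 0.05). By the Wald test 10 stress genes were higher and 3 lower, 2 NRF2 genes higher and 11 lower, 3 cofactors higher and 7 lower, 1 glucocorticoid-induced gene higher and 19 lower, and 5 ion transport genes lower. EdgeR called 6 and 1, 2 and 9, 0 and 5, 2 and 18, and 5 lower. By rank the alveolar (adjusted p = 0.145), stress (0.365), neuronal (0.137) and cofactor (0.0609) lists were not called. With a mean count of at least 100 the stress (adjusted p = 0.0606), cofactor (0.276), NRF2 (0.14) and neuronal (0.962, turning downward) lists were not called. With the Wald statistics the cofactor (adjusted p = 0.168) and neuronal (0.176) lists were not called. Of 9 mitochondrially encoded mRNAs limma called no member for the hairpin in dexamethasone, also adjusted over the list alone and at an unadjusted p under 0.05, edgeR called 1 higher and the Wald test 4 higher. That list was not called by camera (median 0.10, adjusted p = 0.552) and was called upward with the Wald statistics (adjusted p = 0.00405). The epithelial list (camera adjusted p = 0.0708) was called upward with a mean count of at least 100 (adjusted p = 0.029) and the sterol list (camera adjusted p = 0.117) by rank (adjusted p = 0.0268). The TGF-beta list had a median of -0.03, a mean of 0.12 and an upward test (camera adjusted p = 0.709). The count was 2574 by the Wald test that the authors' deposited table implies, of which 43.9% were higher against 57% by limma, and 2900 by edgeR. It was 612 with no filter on low values and 2331 with a mean count of at least 100.

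**Figure D2:**
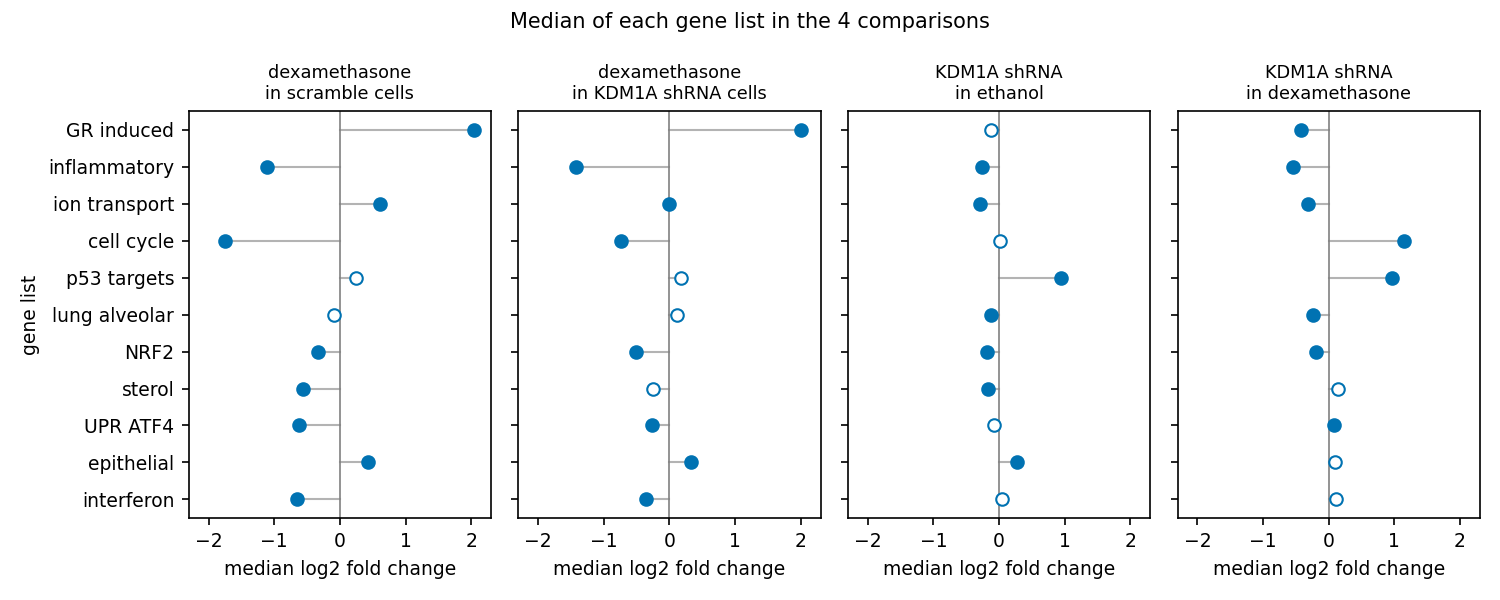
Median log2 fold change (horizontal axis, unitless log2 ratio) of 11 gene lists in the 4 comparisons, from the authors' deposited table in the first 3 panels and from limma in the last. Filled points mark lists with a camera adjusted p under 0.05, and the cell cycle list lies at -1.76, -0.75, 0.02 and 1.14 from left to right.

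The interaction of hairpin and dexamethasone was tested to ask whether the response itself differed between the arms. MYBL2 (ENSG00000101057, chromosome 20), a transcription factor of the cell cycle, had a limma interaction log2 fold change of 2.13 (SE 0.16, adjusted p = 0.019), as its authors' mean count went from 829.5 to 68 with dexamethasone in scramble cells and from 827 to 349.5 in KDM1A shRNA cells. DTL (ENSG00000143476, chromosome 1), a ubiquitin ligase subunit of S phase, was at 2.05 (SE 0.15, adjusted p = 0.0176), CDK1 (ENSG00000170312, chromosome 10) at 1.72 (SE 0.16, adjusted p = 0.0451) and TICRR (ENSG00000140534, chromosome 15), a regulator of replication initiation, at 1.57 (SE 0.14, adjusted p = 0.0322). In all, 9 of 16263 genes passed by limma, 5 with a positive and 4 with a negative interaction, and 1311 had an unadjusted p under 0.05. The 5 calls other than these 4 genes, SFT2D3, MYBPC1, ENSG00000249007, ENSG00000254899 and ENSG00000258085, were named after their values were seen. Their mean counts were at most 44.4, and 3 of them had a group listed at 0.

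**Figure D3:**
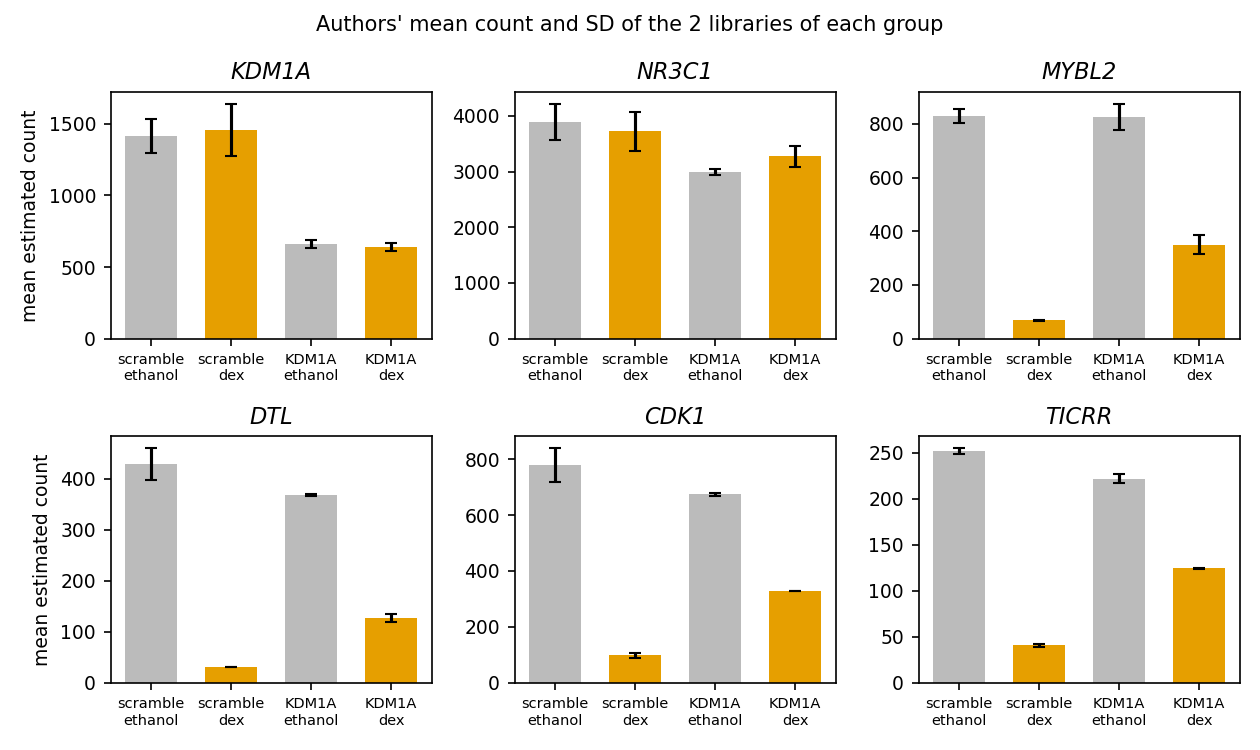
Bars show the authors' mean estimated count of the 2 libraries of each group and error bars the authors' SD, for KDM1A, NR3C1, MYBL2, DTL, CDK1 and TICRR, on axes that start at 0. MYBL2 went from 829.5 to 68 with dexamethasone in scramble cells and from 827 to 349.5 in KDM1A shRNA cells.

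The cell cycle list had an interaction median of 1.12 (camera adjusted p = 1.2e-69), with 1 of 33 genes passing over all genes tested and 29 adjusted over the list alone. Over all genes tested edgeR called 28 of the cell cycle genes higher and the Wald test 21. Glucocorticoid-induced genes had a median of -0.38 (camera adjusted p = 8.75e-11), with 4 of 33 tested members lower adjusted over the list alone. Over all genes tested limma called none of these 33, 11 were lower at an unadjusted p under 0.05, edgeR called 8 lower and the Wald test 13 lower. Sterol genes had a median of 0.38 (camera adjusted p = 3.98e-09) with 7 of 20 higher adjusted over the list alone, and stress genes one of 0.27 (camera adjusted p = 0.00227) with 2 of 22 higher adjusted over the list alone. Over all genes tested limma called no member of either list, 8 sterol and 5 stress genes were higher at an unadjusted p under 0.05, edgeR called 6 and 4 higher, and the Wald test 5 and 5. The scramble ethanol libraries enter the interaction, the scramble response and the hairpin effect in ethanol, so the sterol calls of these are not separate results. Without that group, the sterol list was not called for dexamethasone in KDM1A shRNA cells (camera adjusted p = 0.338) or the hairpin in dexamethasone (0.117). Mesenchymal genes had a median of -0.09 (camera adjusted p = 0.0181, adjusted p = 0.104 with a correlation of 0.05 and adjusted p = 0.13 by rank), with 6 of 23 tested members lower and 2 higher at an unadjusted p under 0.05, no limma call by all genes or adjusted over the list alone, and 3 lower by edgeR. P53 targets had a median of -0.04 (camera adjusted p = 0.743). The mitochondrially encoded mRNAs had a median of 0.11 (camera adjusted p = 0.308, and adjusted p = 0.0502 by rank) and were called upward with the Wald statistics (adjusted p = 1.51e-05). With those statistics the ion transport (adjusted p = 0.00563) and NRF2 (0.00054) lists were also called downward and the hypoxia list upward (0.00845), and with a mean count of at least 100 the ion transport (0.0162) and alveolar (0.0365) lists downward. The TGF-beta list had a median of 0.10, a mean of 0.03 and a downward test (camera adjusted p = 0.852). The count of single genes was 429 with a mean count of at least 100, 422 with a mean-variance trend, 454 by edgeR and 497 by the Wald test that the authors' deposited table implies. Positive interactions made up 291, 271, 290 and 280 of these, in that order, and the others were negative. Of the Wald calls, 184 were genes that rose with dexamethasone in scramble cells. Their response was weaker in KDM1A shRNA cells in 178 and stronger in 6. Another 264 were genes that fell in scramble cells, with 256 weaker and 8 stronger. Genes chosen for a change in scramble cells lean toward a weaker second response by that choice.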

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

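The 3 tests that weigh explanations of the cell cycle pattern were chosen only after that result was seen, while the interaction test itself was planned. A difference between the arms in the response to dexamethasone, by a test of the difference itself, is what brings the following results here. By limma 9 genes passed, among them MYBL2 at 2.13, DTL at 2.05, CDK1 at 1.72 and TICRR at 1.57 on the log2 scale. Among lists the median interaction was 1.12 for cell cycle genes, -0.38 for glucocorticoid-induced genes, 0.38 for sterol genes, 0.27 for stress genes and -0.093 for mesenchymal genes. The call of the mesenchymal list was lost with a correlation of 0.05 (camera adjusted p = 0.104) and by rank, and limma called no member of it.

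Cell cycle genes fell with dexamethasone in both arms and fell less in KDM1A shRNA cells, where a response weaker by 1 common factor is argued against by the slopes of the glucocorticoid-induced and cell cycle lists, which differed by 0.372. The 95% bootstrap interval over genes (0.308 to 0.441) leaves out errors that genes share, and with 1 error shared by all genes of a list the difference less 2 errors was 0.135 if the lists' errors were independent and 0.048 if they added up. This argues only against 1 factor common to both lists. Over all genes called lower in scramble cells the slope was 0.56, and over those called lower in KDM1A shRNA cells 0.735. Both sets were chosen by their calls, so whether cell cycle genes departed from other genes that fell is not settled. A difference in proliferation already there in ethanol is argued against by the list's median between the arms, 0.018 in ethanol (-0.053 to 0.113, and up to 0.348 with a shared error) and 1.14 in dexamethasone. The step in the authors' fit that separates their fold changes from count ratios is argued against by the interaction median from counts alone, 1.12 (0.95 to 1.31), beside 1.11 from their fit. Culture density or other differences between the dexamethasone cultures, an effect of the single hairpin arm other than KDM1A loss, and a biological effect of KDM1A on the response stay open and were not tested.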

How the results depend on the processing

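Chosen only after the data were seen were edgeR on the recovered pairs, the implied Wald test, the slope corrected for error, the slope without cell cycle genes and the list tests on the other fit. The plan had named edgeR for counts per library, so keeping limma as the main test was a choice that the interaction count depends on. No paired analysis was possible because the table carries no replicate identity, and leave-one-out and a replicate block were not run for the same reason. A minimum absolute log2 fold change of 1 left 1354, 714, 301 and 622 genes for dexamethasone in scramble cells, dexamethasone in KDM1A shRNA cells, the hairpin in ethanol and the hairpin in dexamethasone, fewer by construction. For the hairpin in ethanol limma gave 706 genes, 995 with a pseudocount of 10 and 704 with median-of-ratios scaling. For the hairpin in dexamethasone the count was 453 at an adjusted p of 0.01, 612 with no filter, 2331 with a mean of at least 100, 2914 with a trend, 2900 by edgeR and 2574 by the Wald test. For the interaction it was 3 at an adjusted p of 0.01, 56 with a pseudocount of 10, 429 with a mean of at least 100, 422 with a trend, 454 by edgeR and 497 by the Wald test. Apart from the stricter thresholds, the cause was not tested in these data. In the simulated data limma recovered 0 of 100 interactions of 1 on the log2 scale, against 76 with a trend, 79 by edgeR and 84 by the Wald test. Simulated genes lay exactly on the dispersion trend, unlike real ones, so these rates cannot tell which of the real counts is nearer the truth. The degrees of freedom that limma borrowed across genes were 2.44, against 176 with a trend. The limma count of the interaction therefore does not show that few genes had one. The slope of 0.572 moved to 0.767 over genes called in KDM1A shRNA cells, 0.822 over glucocorticoid-induced genes, 0.683 with a mean of at least 100, 0.681 from count ratios with a pseudocount of 10 and 0.602 corrected for error, and was 0.574 without cell cycle genes. PPARGC1A for dexamethasone in KDM1A shRNA cells reversed to -0.694 by limma and with a trend, -0.297 with a pseudocount of 10, -0.696 with median-of-ratios scaling and -0.54 by edgeR, and the cause was not tested. The other total counts over all genes of the 5 comparisons stayed within 1.5 times, while some counts by direction and counts within some lists moved further. Genes higher with dexamethasone in KDM1A shRNA cells went from 1398 to 860 by limma and 855 with median-of-ratios scaling. With no filter the interaction had 8 positive and 5 negative genes. The list tests passed in 41 pairs, 33 with a correlation of 0.05, 41 with a mean of at least 100, 30 rank-based and 46 on the other fit. Of the named gene results of the 3 deposited comparisons 178 kept direction and call by limma, 26 lost the call and 1 reversed. Over all 5 comparisons 261 kept both by edgeR, 4 lost the call and 1 reversed.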

Other observations

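The tests of p53 targets, transcript number and shrinkage below were chosen only after the results were seen, and those of low counts and of neighbouring genes before. Members of KDM1A co-repressor complexes, KDM1A among them, were tested with the hairpin as a list. In ethanol 2 of 20 tested members were higher and 2 lower in the authors' deposited table, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.225), while limma called 1 and 1 and edgeR 4 and 1, and in dexamethasone limma called 1 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.932). Of 29 histone methylation enzymes 2 were lower in ethanol, also adjusted over the list alone (0.886), while limma called no member, with 2 higher and 3 lower at an unadjusted p under 0.05 in the authors' deposited table, and edgeR called 1 higher and 1 lower.

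p53 target genes were higher in KDM1A shRNA cells, with a median of 0.95 in ethanol. An interferon response to the hairpin RNA is argued against as the whole cause by the interferon list. The median of that list in ethanol was 0.046 (95% bootstrap interval over genes -0.067 to 0.141) with 2 of 33 members higher. With 1 error shared by all genes it reached 0.518, beside a lower bound of 0.703 for p53 targets. The 0.518 lay above 0.5 times the p53 target median of 0.95, the limit set for this explanation, so a part of it stays open. An amino acid stress response, which also drives GDF15, SESN2 and TNFRSF10B, is argued against as the whole cause by the 19 p53 targets left without those 3 genes, of which 17 were called at a median of 0.91, while the stress list had a median of -0.08 with 3 members higher, PHGDH at 1.07 and PSAT1 at 0.50 among them, and 6 lower (2 and 1 by limma, 4 and 3 by edgeR), so a part of it stays open. In dexamethasone the stress list was called upward (camera adjusted p = 0.00981, and adjusted p = 0.0767 with a correlation of 0.05), so the argument from its median covers ethanol only. That list also holds unfolded protein response genes. An off-target effect of the hairpin, a difference in culture and a biological effect of KDM1A loss stay open and were not tested.

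The authors' fold changes and the ratios of their mean counts differed gene by gene over 10013 genes, of which 95.2% had a RefSeq transcript count. The median absolute difference was 0.02 on the log2 scale in 1503 genes with 1 transcript and 0.06 in 5040 genes with 5 or more, a ratio of 0.4. Within genes with a mean of at least 1000 the ratio was 0.447, and within 200 to 300 it was 0.606, above the 0.5 set for this explanation, so a correction for transcript length stays an open candidate explanation. The ratio between genes with a mean of at least 1000 and those with 200 to 300 was 0.478, so sampling noise at low counts stays open too. Shrinkage toward 0 is argued against by a slope of 0.982 over genes with 1 transcript.

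A hypothesis that genes changed by the hairpin in ethanol lie near each other was tested by permuting the calls 1000 times over 14596 genes with a position, leaving out pairs under 1 kb apart and pairs whose symbols share a stem. Of 1178 lower genes 227 had another such lower gene within 100 kb, beside a mean of 227.0 over permutations (1-sided permutation p = 0.51). Of 636 higher genes 68 had another such higher gene that near, beside a mean of 66.0 (1-sided permutation p = 0.43). Neither count exceeded its permutations' 95th percentile, 256 and 84.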
